A study of Mus musculus with 2 samples.

How the data were processed

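Poly(A)-selected RNA of mouse G1E cells was sequenced as single-end reads, per the labels, in 2 libraries labelled biological replicates 1 and 2. Both cite the same biosample and form 1 group, so no comparison between conditions was made. Each library came with a gene table and a transcript table, made separately and not pooled. The deposited notes name the assembly mm10 and gene annotation release M4 and derive the tables from alignments to the transcriptome. The aligner, the quantifier and their versions are not given in the sources used here; the column names are those written by RSEM. Library preparation beyond poly(A) selection and whether strand was used are not stated in the sources used here, so reads of overlapping antisense genes may not have been told apart.

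Expected counts, the estimated number of reads per gene or transcript, were deposited without normalisation and need not be whole. TPM values, per the file headers, divide each count by the feature's effective length and were deposited scaled to the same total over all features in a library, spike-in and short RNA entries included. FPKM values were deposited in the same tables, per kilobase of effective length and per total reads. The deposited signal columns of the gene tables give a posterior mean of TPM and the bounds of its credibility interval, whose level the files do not state. The posterior mean lies below the TPM for many genes, so an interval need not contain the TPM it stands beside. The percent column of the transcript tables, per the file headers, is the share of a gene's TPM assigned to each of its transcripts. Effective length equalled length minus a constant that implies reads of 36 nt in replicate 1 and 55 nt in replicate 2. Very short features are weighted up by this correction and took 0.698% of the TPM total in replicate 1 and 7.67% in replicate 2, while protein-coding genes took 84.4% and 75.1%. TPM levels of the same gene are thereby lowered in replicate 2, and the alternative with TPM rescaled over protein-coding genes removes that difference.

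The gene tables held 43346 annotated genes. Symbols, gene types, positions and sequences came from GENCODE release M21 of GRCm38, the same assembly, matched on gene identifiers without their version; 42462 identifiers matched and 884 did not. The symbols Hbb-b1, Hbb-b2 and Ahsp of the fixed lists found no match and were not analysed here. Entries that name no gene were left out of library sizes and tests. They were 26248 entries named by numbers, 96 spike-in sequences and 1 phage sequence, and they held 0.0363% of the counts in replicate 1 and 0.00942% in replicate 2. Expected counts were rounded to whole numbers before any count method.

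The genes named in the text were fixed before the data were examined by this rule: Gata1 and Gata2; of each of 27 gene lists, up to 3 members of highest mean TPM and up to 2 members under 1 TPM; the 20 protein-coding genes of highest mean TPM outside the ribosomal protein and mitochondrial lists; the 5 genes furthest apart between the libraries in each direction among those with at least 100 counts; 20 gene pairs; and the transcripts of 17 genes. Of these, the text gives those that describe each list and leaves some of the 20 highest genes unnamed. Genes named outside the rule are said to be so. The lists covered GATA factors, erythroid regulators and targets, globins, haem and iron, membrane, receptors, other blood lineages, other tissues, proliferation, chromatin, glycolysis, stress, ribosomal, mitochondrial and sex-linked genes, and they overlap in part.

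A gene was called expressed at 1 TPM or more in both libraries. List levels are medians over members of the mean log2(TPM + 1), with the percentile of that median among 10000 random lists of the same size drawn from protein-coding genes. Pair ratios are differences of log2(TPM + 1), whose pseudocount understates ratios of low genes. They were set beside a 95% bound of 1.23, the normal-theory half-width for a mean of 2 libraries derived from the SD between libraries pooled over 10469 expressed genes, which was 0.63. Variation between libraries was estimated with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default expression filter and an intercept-only design, which leaves 1 residual degree of freedom per gene. Genes were called apart at a 2-fold ratio of counts scaled by the TMM library sizes, with 0.5 added to each count, among genes with at least 50 counts in total; no p-value was computed, since 1 library stands against 1. TMM factors were 1.07 and 0.934. GC content was taken over a gene's annotated transcripts, and a lowess trend with a span of 0.3 was subtracted as an alternative. A gene's shared sequence is the share of its transcripts' 36-mers found in another gene. DESeq2 1.42.0 supplied alternative size factors. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

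The steps were tested on counts simulated from the real means and library sizes. With a simulated coefficient of variation of 0.2 and 200 genes changed 4-fold, the comparison of the libraries found 99.0% of the changed genes at least 2-fold apart and called 3.04% of the unchanged genes, with 12871 genes compared. The recovered coefficient of variation was 0.23 over 15279 genes, and with counting noise alone it was 0.0099. The real libraries gave 0.477, and the simulation held no GC trend and no shared reads. The 3.04% is therefore not an error rate for these data.

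Depth sets the precision at the low end. A transcript of 1 kb with 1 count stands at 0.0428 TPM in replicate 1 and 0.0221 TPM in replicate 2. A count of 0 was read as up to 3 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Alternatives covered the pseudocount, FPKM in place of TPM, expression thresholds, count filters, scaling, posterior means, the globins, isoform thresholds and leaving out each library.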

Results

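The data describe poly(A)-selected RNA from G1E cells, an immortalised mouse line of erythroid progenitors that the labels call Gata1-minus. GATA1 is a transcription factor that drives red cell maturation. There was 1 group with 2 libraries, labelled as biological replicates 1 and 2 of the same biosample, and no second condition. Nothing beyond the replicate label shows that the libraries came from separate cultures, so the spread between them may be technical. Replicate 1 held 31645051 expected counts and replicate 2 held 56983558. The questions such a design can answer are which genes were transcribed in these cells, at which level relative to each other, and how closely the libraries gave the same profile. Levels are in TPM, counts over effective length scaled to the same total in each library, and are given as mean ± SD over the 2 libraries.

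Gata1 itself was transcribed. Its mean level was 74.8 ± 18.9 TPM (SD, n = 2), with 88.2 TPM in replicate 1 and 61.4 TPM in replicate 2, above 91.6% of protein-coding genes. The gene (ENSMUSG00000031162.10) lies on the minus strand of chromosome X from 7959260 to 7978071 of GRCm38, and the reads behind it came to 3748 and 5037 expected counts. Almost all of its level was assigned to the transcript Gata1-201, at 96.9% ± 0.42 (SD, n = 2). The labels do not say which part of the gene was disrupted, so its RNA level does not test the Gata1-minus label. Gata2, a GATA factor of stem and progenitor cells, stood at 476 ± 213 TPM (SD, n = 2), on chromosome 6 from 88193891 to 88207032. Zfpm1, which encodes the GATA1 cofactor FOG1, reached 361 ± 201 TPM (SD, n = 2). Gata3 was at 7.86 ± 0.11 TPM (SD, n = 2). Gata5, Gata6 and Zfpm2 stayed under 1 TPM in both libraries, and Gata4 was at 1.69 TPM in replicate 1 and had no count in replicate 2 (Gata3 and Gata4 were named after their values were seen). In the fixed list of GATA factors and FOG cofactors, 4 of 8 members were at 1 TPM or more in both libraries. Gata2 exceeded Gata1 by 2.60 ± 0.30 on the log2 scale (SD, n = 2). This lay beyond 1.23, the 95% bound for a mean pair ratio derived from the pooled SD between libraries.

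Transcription regulators of the erythroid and haematopoietic programme were present as a group, with 20 of 20 list members at 1 TPM or more in both libraries and a median of 86.1 TPM over members (106 TPM in replicate 1 and 51.8 TPM in replicate 2). The list's median lay above those of all 10000 random lists of the same size, a percentile of 100. The haem, proliferation, glycolysis and chromatin lists also reached 100, so this is not particular to these regulators. The globin list lay at 73.2 and the list of GATA factors and FOG cofactors at 72.2. Gfi1b, a repressor needed for red cell and platelet formation, led at 564 ± 284 TPM (SD, n = 2). Ldb1, which bridges the complex of GATA1, TAL1 and LMO2, followed at 316 ± 170 TPM, and Nfe2, a globin and platelet gene activator, at 274 ± 210 TPM (SD, n = 2 for both). Klf1, the erythroid Krüppel-like factor, stood at 162 ± 30.2 TPM and Tal1 at 136 ± 2.85 TPM (SD, n = 2 for both). Spi1, the myeloid regulator PU.1, was at 76.6 ± 41.7 TPM (SD, n = 2). In TPM these genes except Klf1 and Tal1 differed by more than 2-fold, all higher in replicate 1, but on TMM-scaled counts only Nfe2 did. The log2 ratios of counts, replicate 2 over replicate 1, were -1.07 for Nfe2, -0.85 for Ldb1, -0.79 for Gfi1b and 0.03 for Spi1.

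Genes known to be repressed when GATA1 is present were at higher levels, as a list, than genes known to be activated by it. All 8 repressed-list genes were at 1 TPM or more in both libraries with a median of 211 TPM, led by Gata2, Myc at 406 ± 177 TPM and Lyl1 at 257 ± 52.5 TPM (SD, n = 2 for both). Kit, the stem cell factor receptor, was at 166 ± 36.3 TPM (SD, n = 2) and Myb at 203 ± 122 TPM (SD, n = 2). The 22 measured activated-list genes were also all at 1 TPM or more in both libraries, with a median of 68.2 TPM. They ranged from the alpha globins and Bnip3l, a mitophagy receptor at 456 ± 187 TPM (SD, n = 2), to Tmod1 at 1.22 ± 0.10 TPM (SD, n = 2). The red cell anion exchanger Slc4a1 was at 1.62 ± 0.88 TPM (SD, n = 2; this gene and Tmod1 were named after their values were seen). The difference of the list medians, activated minus repressed, was -1.64 ± 0.45 on the log2 scale (SD, n = 2), and 4.34% of 10000 random splits of the members gave a difference as low. Different genes have different levels for many reasons, so this describes these libraries and tests no effect of GATA1. Without the globins the difference was -2.29.

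**Figure D1:**
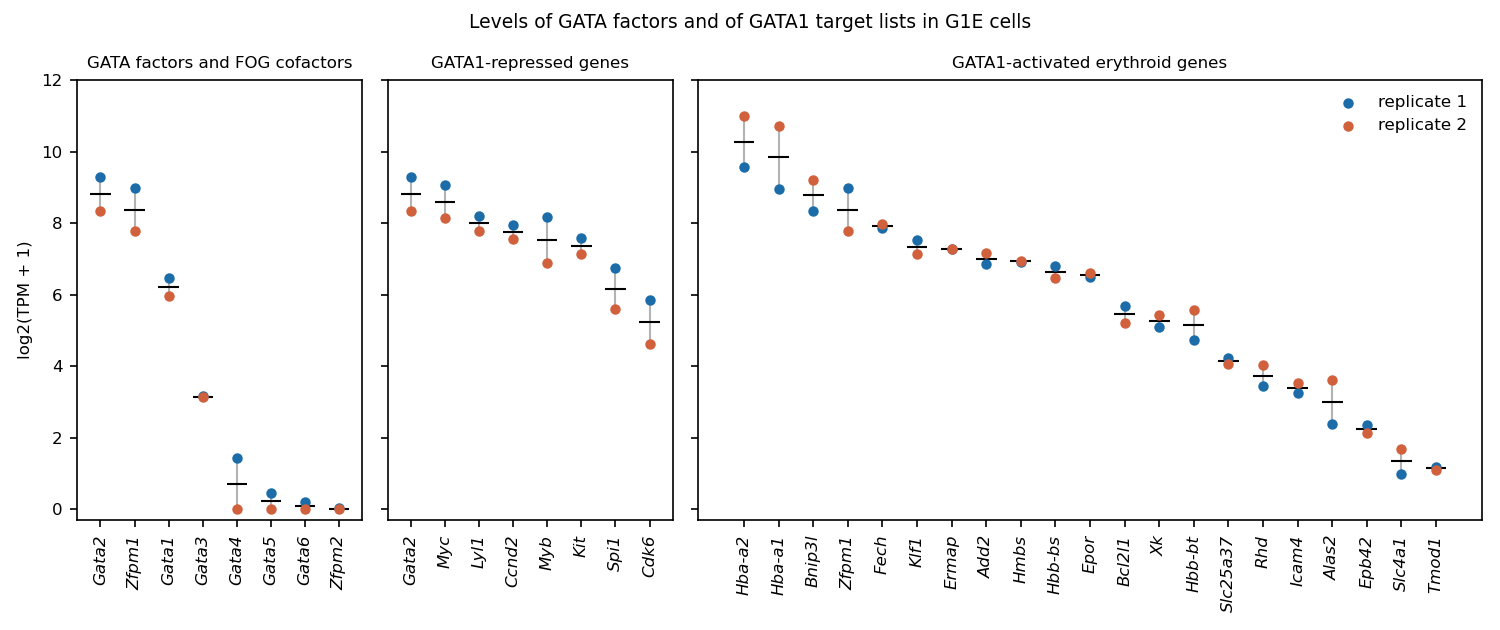
Level of the measured members of the GATA factor list, the GATA1-repressed list and the GATA1-activated list (1 member of the last is not shown), as log2(TPM + 1) on the vertical axis; coloured points are the 2 libraries, black bars their mean and grey lines their range. Gata1 sits at 74.8 TPM on average and Gata2 at 476 TPM, and the activated list extends from Hba-a2 at 1388 TPM down to Tmod1 at 1.22 TPM.

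Adult alpha globin was the most abundant globin RNA, and no embryonic globin reached 1 TPM in both libraries. Hba-a2 stood at 1388 ± 893 TPM and Hba-a1 at 1089 ± 839 TPM (SD, n = 2 for both), on chromosome 11. Replicate 2 held more of both, with 2019 against 757 TPM for Hba-a2 and 1683 against 496 TPM for Hba-a1. Hbb-bs, an adult beta globin, was far lower at 98.8 ± 16.4 TPM (SD, n = 2). The embryonic Hba-x was at 0.050 ± 0.014 TPM (SD, n = 2) on 1 count per library, Hbb-bh2 had 0 counts in both, and Hbb-bh1 was at 0.07 TPM on 1 count in replicate 1 and 1.14 TPM on 29 counts in replicate 2. Of 10 measured globin genes, 5 were at 1 TPM or more in both libraries. The alpha globin genes share 74.6% and 91.7% of their 36-mers with other genes, so the division of reads between Hba-a1 and Hba-a2 is uncertain. Hbb-bs shares 54.1%, so its level is uncertain as well. Hbb-bt, also on the list, was at 36.1 ± 15.1 TPM (SD, n = 2) and shares 59.1% of its 36-mers. It was named after its value was seen. The listed symbols Hbb-b1 and Hbb-b2 found no match, so no level is given under these names.

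Haem synthesis genes were expressed throughout, with 12 of 12 list members at 1 TPM or more in both libraries and a median of 77.7 TPM. Cpox, coproporphyrinogen oxidase, was highest at 370 ± 115 TPM, followed by Fech, which inserts iron into the ring, at 241 ± 12.7 TPM and Alad at 192 ± 16.2 TPM (SD, n = 2 for all). The erythroid first enzyme Alas2 was low, at 4.21 TPM in replicate 1 and 11.4 TPM in replicate 2, against 15.3 and 10.4 TPM for the housekeeping Alas1. Iron handling genes were all expressed as well, 13 of 13, led by the ferritin chains Fth1 at 4297 ± 362 TPM and Ftl1 at 3442 ± 215 TPM and by the iron sensor Aco1 at 158 ± 21.8 TPM (SD, n = 2 for all). Ftl1 shares 55.9% of its 36-mers with other genes. Of the 19 red cell membrane and skeleton genes, 18 were at 1 TPM or more in both libraries, with a median of 37.9 TPM. Ermap at 153 ± 0.93 TPM, beta spectrin Sptb at 141 ± 42.2 TPM and Epb41 at 140 ± 7.47 TPM led this list (SD, n = 2 for all), and Dmtn was its 1 member under 1 TPM.

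Receptors and signalling genes of the progenitor stage were present. Stat5a was at 166 ± 30.6 TPM, Cish, a STAT5 target, at 139 ± 51.0 TPM and the erythropoietin receptor gene Epor at 93.1 ± 5.13 TPM (SD, n = 2 for all). Csf1r, the macrophage colony-stimulating factor receptor, was under 1 TPM in both libraries. In this list 9 of 14 members were at 1 TPM or more in both.

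Markers of other cell types were mostly under 1 TPM, least so in the megakaryocyte and platelet list. That list had a median of 1.13 TPM and 6 of 16 members at 1 TPM or more in both libraries. They included Nbeal2 at 47.4 ± 11.9 TPM, the integrin Itga2b at 25.4 ± 9.06 TPM and platelet factor gene Pf4 at 12.5 ± 1.60 TPM (SD, n = 2 for all). Also among them were Gp1ba at 9.0 ± 7.4 TPM, Gp5 at 8.9 ± 0.9 TPM and Gp9 at 7.0 ± 0.8 TPM (SD, n = 2 for all). These 3 genes were named after their values were seen. Gp1bb had no count in either library, a value made uncertain by the 36-mers it shares with another gene, and Gp6 was under 1 TPM. Mast cell and basophil markers numbered 3 of 12 in both libraries, with the proteoglycan gene Srgn at 17.0 ± 6.78 TPM, Cpa3 at 9.98 ± 7.52 TPM and Hdc at 2.25 ± 0.72 TPM (SD, n = 2 for all), while Fcer1a and Mcpt8 had at most 1 count. Granulocyte and monocyte markers numbered 3 of 18, with Cebpe at 10.2 ± 5.89 TPM, Lyz2 at 9.43 ± 8.80 TPM and Cd68 at 8.78 ± 4.26 TPM (SD, n = 2 for all). Mpo was under 1 TPM and Elane had no count. The lymphoid list had 1 of 17 members in both, Lck at 2.33 ± 0.22 TPM (SD, n = 2), and the stem cell list 1 of 15, Erg at 2.92 ± 1.10 TPM (SD, n = 2). Hoxa9, Hoxb4 and Cd3d were under 1 TPM. Of the endothelial list only Egfl7 was at 1 TPM or more in both, at 123 ± 71.7 TPM (SD, n = 2), with Cdh5 and Kdr under 1 TPM.

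No member of the pluripotency, fibroblast or other-tissue lists reached 1 TPM in both libraries. Pou5f1, Nanog, Col1a1, Col1a2, Alb and Ttr were all under 1 TPM, and the medians of these lists were 0.11, 0.055 and 0.043 TPM, which come from replicate 1, since none exceeded 0.005 TPM in replicate 2. In replicate 1 alone 4 members exceeded 1 TPM, Lin28a at 2.30, Dppa5a at 1.71, Snap25 at 1.08 and Fn1 at 1.07 TPM. In replicate 1, protein-coding genes without shared 36-mers and without a count in replicate 2 carried a low level of reads equal to 0.11 TPM, so values of that size there do not separate expression from background. A count of 0 allows up to 0.128 TPM for a transcript of 1 kb in replicate 1 and 0.0662 TPM in replicate 2, for counting error only. Of the foetal and embryonic list, 3 of 10 members were expressed in both, namely the RNA-binding protein genes Igf2bp1 at 31.6 ± 11.7 TPM, Igf2bp3 at 18.5 ± 0.11 TPM and Lin28b at 5.13 ± 1.24 TPM (SD, n = 2 for all). Hmga2 and H19 were under 1 TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty did not exceed 0.19 TPM in either library (Eif2s3y was named after its value was seen), although the labels give the sex as male, and Xist was at 0.55 ± 0.11 TPM (SD, n = 2).

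**Figure D2:**
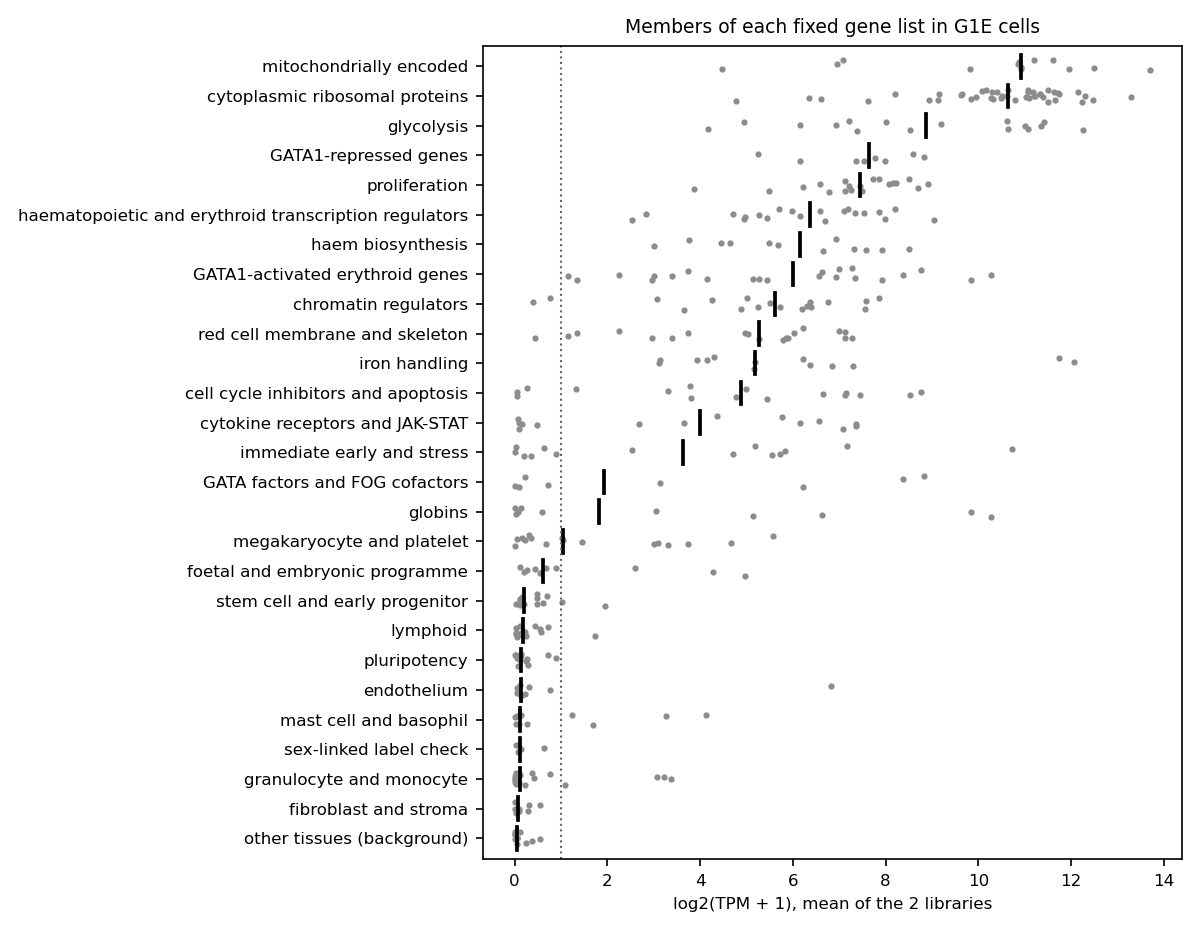
Mean log2(TPM + 1) over the 2 libraries of each measured member of the 27 fixed gene lists (grey points, spread vertically for visibility), with the list median as a black bar and the dotted line at 1 TPM. Ribosomal, glycolytic, proliferation, haem and erythroid regulator lists lie to the right, while the globin list has a median of 1.82 on this axis. The pluripotency, fibroblast and other-tissue lists have medians of 0.11 TPM or less.

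The cells carried abundant RNA for growth and division. All 19 proliferation genes were expressed in both libraries with a median of 175 TPM, led by the replication factors Pcna at 481 ± 24.6 TPM, Mcm3 at 414 ± 9.69 TPM and Mcm5 at 364 ± 64.5 TPM (SD, n = 2 for all). All 16 glycolysis genes were expressed, with a median of 487 TPM, and Gapdh at 4914 ± 538 TPM, Aldoa at 2789 ± 778 TPM and Pkm at 2627 ± 288 TPM were the highest (SD, n = 2 for all). Of 16 cell cycle inhibitor and apoptosis genes, 13 were expressed, among them Trp53 at 378 ± 116 TPM and Bax at 177 ± 48.6 TPM (SD, n = 2 for both). Cdkn1c and Cdkn2a, genes of cell cycle inhibitors, were under 1 TPM in both. Chromatin regulators were expressed in 16 of 18 cases, with Dnmt1, the maintenance DNA methyltransferase, at 239 ± 89.9 TPM, Chd4 at 192 ± 26.9 TPM and Mta2 at 191 ± 38.2 TPM (SD, n = 2 for all), and Tet1 under 1 TPM. Of 14 immediate early and stress genes, 8 were expressed. Hsp90aa1 stood at 1708 ± 341 TPM, Hspa5 at 143 ± 1.20 TPM and Ier2 at 57.4 ± 17.0 TPM (SD, n = 2 for all), while Fosb and Jun were under 1 TPM.

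All 45 cytoplasmic ribosomal protein genes were expressed, with Rpl41 at 10166 ± 1545 TPM, and 12 of 13 mitochondrially encoded genes, with mt-Atp8 at 13395 ± 916 TPM (SD, n = 2 for both). Among the 20 most abundant protein-coding genes outside these lists were Eef1a1, an elongation factor, at 10626 ± 1124 TPM, Rack1 at 5166 ± 1215 TPM, Ptma at 4284 ± 209 TPM and the metallothioneins Mt1 at 3931 ± 25.3 TPM and Mt2 at 2407 ± 69.5 TPM (SD, n = 2 for all). Gm10800, a predicted gene on chromosome 2 from 98666547 to 98667301, was also one of the 20 but on replicate 1 alone, with 19572 TPM there against 79.97 TPM in replicate 2. It shares 38.2% of its 36-mers with other genes. Replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail, summed to 6323 ± 671 TPM (SD, n = 2) over 67 genes. The sums were 6798 TPM in replicate 1 and 5849 TPM in replicate 2. Hist1h2ao alone held 4853 and 2039 TPM of these, so the sum over the other histone genes was higher in replicate 2. Hist1h2ao shares 93.7% of its 36-mers with other genes, so the division of reads among them is uncertain.

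Across the whole annotation 10469 genes were at 1 TPM or more in both libraries, of which 9118 were protein-coding. Replicate 1 alone reached 1 TPM for a further 627 protein-coding genes and replicate 2 alone for 273. At 1 rounded count or more the difference was wider, with 18169 protein-coding genes in replicate 1 against 13730 in replicate 2, the library with more reads.

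Of 20 gene pairs fixed before the data were examined, 14 differed at least 2-fold in the same direction in both libraries, and 14 exceeded the 95% bound of 1.23 on the log2 scale. Ldha exceeded Ldhb, the other lactate dehydrogenase chain, by 10.75 ± 0.35 on the log2 scale, Myc exceeded Mycn by 8.58 ± 0.62, Zfpm1 exceeded Zfpm2 by 8.36 ± 0.83 and Dnmt1 exceeded Dnmt3a by 7.09 ± 0.41 (SD, n = 2 for all). Runx1 exceeded Runx3 by 32.1-fold as a ratio of TPM + 1 (SD of the log2 ratio 0.32, n = 2). The pseudocount makes this lower than the ratio of their levels. Runx1 stood at 86.0 TPM in replicate 1 and 29.8 TPM in replicate 2, and Runx3 at 1.32 and 0.12 TPM. On the log2 scale Pkm exceeded Pklr by 4.42 ± 0.08 and Bcl2l1 exceeded Bcl2 by 4.13 ± 0.16 (SD, n = 2 for both). Tet2 over Tet1 was 2.67 ± 0.13, Ezh2 over Ezh1 was 2.55 ± 0.24 and Stat5a over Stat5b was 1.60 ± 0.07 (SD, n = 2 for all). The lower member came first for Cdk6 over Cdk4 at -4.71 ± 0.54 and Hba-x over Hba-a1 at -9.77 ± 1.26 (SD, n = 2 for both). Inside the bound lay Klf1 over Spi1 at 1.17 ± 0.55, Kit over Epor at 0.81 ± 0.40, Ccnd3 over Ccnd2 at 0.68 ± 0.24, Tal1 over Lyl1 at -0.90 ± 0.27 and Hbb-y over Hbb-bh1 at -0.57 ± 0.67 (SD, n = 2 for all). A robust estimate of the spread gives a bound of 0.98, which Klf1 over Spi1 exceeds, and with a pseudocount of 0.1 Hbb-y over Hbb-bh1 was -1.96. Alas2 over Alas1, at -0.77 ± 1.24 (SD, n = 2), changed direction between the libraries, from -1.64 in replicate 1 to 0.11 in replicate 2. With 2 libraries an exact sign-flip permutation test cannot give a two-sided p below 0.5, so none was run. Ratios with a low member depend on the pseudocount of 1.

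Transcript tables assigned most of the level of Gata2 to Gata2-201, at 95.8% ± 2.20, and of Pkm to Pkm-201, at 98.3% ± 0.25 (SD, n = 2 for both). Kit was led by Kit-201 at 72.4% ± 6.37, Lmo2 by a transcript of 848 nt at 51.5% ± 1.77, Runx1 by Runx1-203 at 72.2% ± 15.9 and Epb41 by Epb41-206 at 42.1% ± 9.28 (SD, n = 2 for all). Myb was led by Myb-202, annotated as a retained intron, at 74.6% ± 16.1 (SD, n = 2). The leading transcript was the same in both libraries for 12 of the 17 genes fixed for this comparison. It differed for Bcl2l1, where Bcl2l1-209 led with 61.1% in replicate 1 and Bcl2l1-201 with 62.4% in replicate 2, and for Mcl1, Dnmt1 and Ank1. It also differed for Cdkn2a, but on 1 count in replicate 1 and 14 in replicate 2, too few to show a change. Among 4793 genes with several annotated transcripts and at least 10 TPM in both libraries, the leading transcript agreed in 70.1% (3358 genes; 95% Wilson interval 68.7% to 71.3%, counting error only). Where the leading transcript held at least 60% in each library, agreement was 93.4%. Single-end reads of different length, 36 and 55 nt as implied by the effective lengths, resolve overlapping transcripts only in part.

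The libraries gave similar rankings but differed well beyond counting noise. Over 13209 genes at 1 TPM or more in either library, log2(TPM + 1) correlated across genes with Pearson's r of 0.891 and Spearman's rho of 0.888, where genes are not independent replicates. A chi-square of the counts against proportional libraries was 351 per degree of freedom over 18731 genes, where counting noise alone gives close to 1. The common biological coefficient of variation from edgeR was 0.477 over 12457 genes. Of 12414 genes with at least 50 counts, 4035 (32.5%) were at least 2-fold apart, 2772 of them higher in replicate 2 and 1263 higher in replicate 1. That share of 68.7% higher in replicate 2 depended on the scaling and was 58.6% with library size alone and 47.6% with the ratio of TPM values. The median log2 ratio over the genes compared was 0.28 with TMM scaling, 0.08 with library size and -0.07 with TPM.

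The ratio between the libraries varied with the base composition of the genes. Protein-coding genes with transcripts of up to 40% GC had a median log2 ratio, replicate 2 over replicate 1, of 1.69 over 376 genes, against -0.10 over 2053 genes of 55 to 60% GC. Spearman's rho of the ratio with GC content was -0.48 across 10467 genes. Among the lists, 4 of 5 globin genes, 16 of 45 ribosomal protein genes, 8 of 22 GATA1-activated genes, 2 of 20 transcription regulators and 1 of 16 glycolysis genes with enough counts were at least 2-fold apart. The ribosomal and activated shares, 35.6% and 36.4%, lie near the 32.5% over all genes compared. Other lists with few genes compared were also high, with 4 of 5 granulocyte and monocyte and 5 of 7 stem cell genes apart. These shares take no account of direction. Of the activated list 20 genes were higher in replicate 2 and 2 lower, with a median log2 ratio of 0.62. Of the repressed list 1 was higher and 7 lower, with a median of -0.28. Of the ribosomal list 37 were higher and 8 lower, with a median of 0.67. The median over all genes compared was 0.28 with TMM scaling. The cause of these directions was not tested. Ranked by the ratio with 0.5 added to each count, the genes furthest apart were mostly pseudogenes and predicted genes. Higher in replicate 1 were Gm14513 by at least 2047-fold, Gm13339 by 1357-fold, Gm26602 by at least 514-fold, Gm5244 by at least 270-fold and Rpl7a-ps11 by at least 164-fold. Higher in replicate 2 were Rps13-ps2 by at least 2412-fold, Gm10163 by at least 1731-fold, mt-Nd3 by at least 1392-fold, Gm8430 by at least 1279-fold and Gm6682 by at least 904-fold. Bounds replace a count of 0 with 3 counts in that library, so some lie below the ratios of genes not named here. Of these 10 genes, 7 share more than 60% of their 36-mers with another gene, mt-Nd3 among them.

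**Figure D3:**
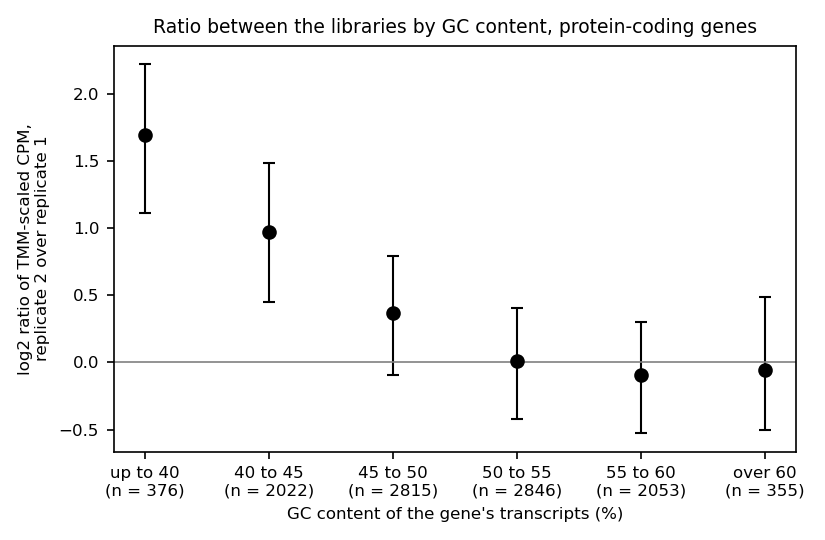
Median log2 ratio of TMM-scaled counts, replicate 2 over replicate 1 (vertical axis), for protein-coding genes with at least 50 counts grouped by the GC content of their transcripts (horizontal axis, percent); whiskers span the quartiles. The median is 1.69 up to 40% GC and lies near 0 above 50% GC, with 0.01 at 50 to 55%; the median over all genes compared is 0.28 with this scaling and -0.07 with TPM, so the sign near 0 depends on the scaling.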

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

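Signal appeared in entries outside the gene measurements. The 26248 number-named entries, features of 61 to 259 nt that carry no gene name in the files, held 11476.6 expected counts in replicate 1 and 5365.16 in replicate 2. Taken singly, 913 of them in replicate 1 and 318 in replicate 2 were above the 3 counts that a count of 0 allows, with at most 117 and 252 counts in an entry. The spike-in and phage sequences did not exceed 1 count in either library. The count per entry was added after the sums were seen. What the number-named entries are was not tested, and no control samples exist to set a background.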

How the results depend on the processing

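The alternatives on protein-coding genes for the coefficient of variation and the genes apart, and those on unshared 36-mers, rescaled TPM, the GC trend and the subtracted median were chosen after the data were seen. Gata1 stayed between 56.98 and 93.1 across units, scalings and single libraries. Expressed genes numbered 7933 to 12337, lists with at least 0.5 of their members expressed 15 to 17, and 2-fold pairs 14 to 17. The list difference kept its direction, from -1.33 to -1.97 with a library left out, and was -2.29 without globins, whose alpha genes are high members of the activated list. Pearson's r between libraries was 0.810 with a pseudocount of 0.1, 0.956 without a filter, 0.940 on TMM-scaled counts and 0.924 for unshared protein-coding genes. The coefficient of variation was 0.459 with library size alone, 1.06 without the filter and 0.432 for protein-coding genes. Genes apart numbered 2659 at 200 counts or more (26.5% of those compared; 83.0% of them higher in replicate 2), 9072 at 10 or more (48.4%; 37.1%) and 6489 at a 1.5-fold ratio, so the share apart and its direction depend on the filter. Leading transcripts agreed in 93.4% where each held 60% or more, a subset chosen for dominance. Alas2 over Alas1 was -1.64 without replicate 2 and 0.11 without replicate 1; the cause was not tested. The other 19 pairs kept their direction, but a pseudocount of 0.1 moved 10 of 20, such as Zfpm1 over Zfpm2 to 11.56, Tet2 over Tet1 to 4.68, Runx1 over Runx3 to 6.50 and Bcl2l1 over Bcl2 to 4.75, and 15 of 27 list medians. Low levels are limited by depth and, in replicate 1, by background reads.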

Other observations

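The tests of the combined GC, sharing and depth explanation and both tests on Y-linked genes were chosen after the result was seen; the others were fixed before it. Genes in this part were named after their values were seen.

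Among genes with no shared 36-mers and at least 1000 counts, the 8 furthest apart in each direction were examined. Of those higher in replicate 1, the integrin gene Itga5 stood at 55.2 TPM in replicate 1 and 4.28 TPM in replicate 2, the galectin gene Lgals9 at 1384 and 163 TPM, the urea transporter gene Slc14a1 at 14.5 and 1.31 TPM and Parm1 at 17.8 and 0.88 TPM. In the other direction 7 of the 8 genes, among them Zfp654 at 0.76 and 5.05 TPM, have transcripts of 35.8 to 42.0% GC, while Rasal1, at 4.50 and 24.9 TPM, has 60.3%. Of list members, the immediate early gene Egr1 was at 83.1 TPM in replicate 1 and 14.7 TPM in replicate 2, while the transferrin receptor gene Tfrc was at 48.4 and 139 TPM and the mast cell gene Cpa3 at 4.66 and 15.3 TPM. Tfrc and Cpa3 have transcripts of 39.4% and 41.0% GC. Protein-coding genes had a median log2 ratio of 1.69 up to 40% GC and 0.97 at 40 to 45%. The predicted genes around Gm10800 on chromosome 2 and from 3000282 to 3038316 on chromosome 9 had far higher levels in replicate 1, except Gm10720 with 2 counts in each library, with 4214 TPM for Gm10801 against 20.99 TPM in replicate 2 and 1017 TPM for Gm10717 against 3.79 TPM. These entries share from 31.8% (Gm10801) to 93.6% (Gm10720) of their 36-mers with other genes, so the division of reads among them is uncertain.

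A large share of genes, 32.4% of the 12330 with a GC value, was at least 2-fold apart between libraries of the same cells. After the GC trend was subtracted 2820 genes were apart against 3989 before, 70.7% of the number though not all the same genes, and 42.5% of them were higher in replicate 2; part of that drop is recentring, since subtracting the median ratio alone gave 3607. Genes with no shared 36-mer had 78.0% of the overall share, and genes with at least 1000 counts 70.7% of it, so each factor may account for part and none reached the 50% set beforehand as the mark of a main cause. Among the 2204 unshared genes with at least 1000 counts, 420 were apart before and 227 after the trend was subtracted. The remaining share was 31.8% of the overall one, under the 50% mark. Each factor alone had already lowered the count or the share, so stacking them was likely to pass that mark. Part of this drop may also be recentring, so the combined test does not show that the factors acted together. No biological explanation was tested, since the labels name no difference between the libraries, and a difference in culture or in library preparation stays open.

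Replicate 1, the library with fewer reads, carried reads in protein-coding genes that had no count in replicate 2, at 2.57 counts per kb over 2830 genes without shared 36-mers. This was 85.7% of the density over all 7726 such genes, the 2830 included. It argues against exact sequence shared between annotated genes as the main source. Reads from repeats outside the annotation, or from copies that differ by a few bases, are not covered by this measure. The density of X-linked genes was 0.422 times the autosomal one (95% range over genes 0.332 to 0.523), and silent lincRNA, antisense and processed pseudogene entries had 2.93, 2.97 and 2.87 counts per kb. Genomic DNA from cells with 1 X chromosome is therefore a candidate source, as a hypothesis, although olfactory, vomeronasal and trace amine receptor genes had only 0.965 counts per kb, below what an even cover of the genome would give. Low-level transcription that differs by chromosome was not tested and stays open.

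The labels give the sex as male, yet Ddx3y, Eif2s3y, Kdm5d and Uty did not exceed 0.19 TPM in either library. Only 2.96% of their 36-mers occur in another gene, so reads could have been told apart, which argues against a loss of Y signal to gene copies. In replicate 1 these genes had 1.11 times the autosomal density of silent genes, with a 95% range over the genes of 0.182 to 1.59, so absence of the Y chromosome may hold or not. The range over genes was chosen in place of a counting interval after the counts had been seen. The counting interval, 0.767 to 1.53, lay above the bound of 0.25. Neither range can decide on absence, since this density reflects Y copies only if the background reads are genomic DNA. That source is itself a hypothesis. Kdm5d held 27 of the 35 counts, while Usp9y, also on Y, had 0 counts over 8094 nt. Kdm5d shares 4.67% of its 36-mers with other genes, and whether reads of other genes were placed on it was not tested.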
